A study of Mus musculus with 18 samples.

How the data were processed

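RNA from 3T3-F442A adipocytes was measured on 18 Affymetrix MG_U74Av2 arrays. 3T3-F442A is a mouse preadipocyte line that can be turned into fat-storing cells in culture. Per the labels, cells were kept as control or given growth hormone (GH) for 30 min, 4 h or 48 h, which makes 6 groups of 3 arrays, with 1 array of each group in each of 3 numbered experiments. Groups were taken from the titles, because the titles fill every group once per experiment. For 3 samples the description names another group than the title: the GH 30 min sample of experiment 1 is described as GH 48 h, the control 48 h sample of experiment 3 as control 4 h, and the GH 4 h sample of experiment 3 as GH 30 min. Socs3 and Fos, the transcripts with the clearest early levels, go with the titles in the GH 30 min and GH 4 h arrays concerned. Controls at 4 h and 48 h had too few clear differences to place the other array, and the closing section gives the counts without the 3 arrays where they move. Nothing in the labels says that the replicates came from separate cultures beyond the words experiment 1, 2 and 3, so p-values measure the spread between these samples.

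The deposited table holds 1 signal intensity per probe set and array, on a linear scale. The labels and the files used here do not state the summary method, the scaling or the software behind these intensities. The mean signal with 2% of the probe sets left out at each end was 500.3 on every array, so the authors' values were already scaled between arrays. A transcript that fills a larger share of the RNA on an array therefore lowers the others slightly, and changes are relative to the bulk of the probe sets. The array information files name the chip type and hold no date or scanner entry, so no processing batch other than the experiment number could be examined. The table holds 12488 probe sets. The 66 control probe sets of the manufacturer were left out of the tests, which leaves 12422. Of these, 10833 carry 1 gene symbol in the platform table, 396 several and 1193 none, and probe sets with several or none are called unnamed here. Symbols were checked by gene identifier against the reference gene table of assembly GRCm38.p6, where 10817 matched and 0 needed a newer symbol. No genome position was taken from it, since the table of signals names no assembly. Probe sets whose names end in _f_at (1075), _r_at (901) or _s_at (371) can read related transcripts or were designed under relaxed rules, and genes known here from such a probe set are named with that limit. For 2073 of the 8251 genes with more than 1 probe set, the one with the highest mean signal stands for the gene.

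Signals were analysed as log2(signal + 25), where 25 is the 20th percentile of all signals above 0. Fold changes are on this scale, which makes changes of dim transcripts smaller than the ratio of their signals. The array medians on that scale differed by 0.256, below the limit of 0.3 set for a further normalization, so none was applied. Array medians ran from 148.7 to 182.4 signal units. The 19 probe sets for yeast and Bacillus transcripts, which should find no target in mouse RNA, had a median signal of 15 and a highest value of 106 over 342 values, and a gene whose group means both lie below 106 is named as near background. None of the 66 control probe sets differed between GH and control at any time (0 by limma, without or with the block described below). The ratios of 3-prime to 5-prime signal were 0.724 to 0.931 for Gapdh and 1.22 to 2.04 for Actb, and each array's mean correlation with the others was 0.946 to 0.967. The number of arrays, 3 per group, limits the precision of every value.

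Each probe set was tested with limma's moderated test, two-sided, in 1 model of the 6 groups with 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the 12422 probe sets of a comparison, with a threshold of 0.05. There are 8 comparisons: GH against control at each time, the differences between these GH effects, and the later against the earlier controls. Whether the experiment number pairs the samples was checked on each array's deviation from its group mean. In the 3 GH comparisons, the GH and control arrays of 1 experiment correlated at 0.151 to 0.457 across probe sets, and over all 45 same-experiment combinations the correlation was 0.0552 to 0.472. Every pair of the GH comparisons is over the limit of 0.1, so the numbers are taken to pair the samples. At 48 h the pairing is less clear, since the control array of experiment 1 correlated more with a GH array of another experiment (0.213) than with its own (0.166), and experiment 2 had 0.124 and 0.151. The model with the experiment as a replicate block, with 10 residual degrees of freedom, was an alternative fixed in advance. Its values are given where it changes a call or moves a count by more than 1.5 times, as at 4 h, where it gives 45 probe sets against 15 without it.

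Lists of related genes were tested with camera, which compares the list with the other genes and here assumed a correlation of 0.01 between members, over the 8251 genes, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. The same test with a correlation estimated from the residuals, and fry, which asks whether members move on balance in 1 direction without reference to other genes, were alternatives. The lists were immediate early genes, GH receptor and JAK-STAT components, SOCS family and STAT5 targets, IGF axis, insulin signalling and glucose transport, fatty acid and triglyceride synthesis, sterol synthesis and uptake, lipolysis and lipid droplet, adipocyte differentiation markers, fatty acid oxidation and thermogenesis, glycolysis and hypoxia response, oxidative phosphorylation, interferon-response genes, inflammatory and acute-phase genes, extracellular matrix, preadipocyte and fibroblast markers, macrophage and leukocyte markers, endothelial and muscle markers, cell cycle and DNA replication, unfolded protein and integrated stress response, heat shock response, ribosome biogenesis and polyamine synthesis, housekeeping genes, and GH response genes followed at every time. Some genes are in more than 1 list. Listed names were matched through older symbols only where the name is not itself a current symbol.

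The groups, comparisons, tests, thresholds, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those marked otherwise. By that rule, each comparison of GH with control names up to 12 genes per direction past the threshold with the same sign in 3 of 3 experiments, filled to 6 per direction with the genes of lowest unadjusted p, the followed GH response genes, and up to 4 members of each list with the lowest adjusted p. Other comparisons name up to 6 genes per direction. Named outside the rule, after their values were seen, were further list members past the threshold over the list alone, genes that pass only with the block, the probe sets that are not a gene's brightest, and past-threshold genes beyond the largest 12.

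The model was tested on simulated data with 200 changed probe sets, 20 times per comparison, with normal noise of each probe set's own residual spread. For GH against control at 30 min, 4 h and 48 h, it found 29.3%, 30.8% and 27.4% of probe sets changed 2-fold and 66.6%, 65.6% and 68.1% of those changed 4-fold. Among the brighter part of the probe sets, 90.7%, 91.1% and 91.2% of the 4-fold changes were found. False calls made up 6.72%, 5.6% and 5.35% of all calls. In 20 simulations without any effect, made by shuffling whole arrays of residuals, camera with the preset correlation still called a mean of 3.4, 3.5 and 4.15 lists at the 3 times, and at most 12, 11 and 15. The shuffling does not keep the experiments balanced between GH and control, as the real groups are. These numbers can therefore be too high for the real design. With the estimated correlation the means were 0, 0.05 and 0, and a list shifted by 0.5 log2 was called in 19, 20 and 20 of 20 simulations.

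Alternatives were the block, the arrays of the compared groups alone, quantile normalization, leaving out the 3 arrays with conflicting labels, groups from the descriptions, leaving out each array and each experiment, limma with a trend or robust variance, removal of probe sets with a mean below the 25th or 50th percentile, a halved or doubled pseudocount, other probe sets of a gene and, for lists, the estimated correlation, fry and the mean over all probe sets of a gene. Added after the data were seen were the block together with the omission of the 3 arrays or of experiment 3, and the block together with the estimated correlation. Analyses used R 4.3.3 with limma 3.58.1, data.table version 1.17.8 and statmod 1.5.0, and figures Python 3.11.15 with matplotlib 3.10.9.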

Results

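GH changed the RNA of 3T3-F442A adipocytes in a time-dependent way on these 18 arrays. By limma, 5 probe sets differed between GH and control at 30 min, 15 at 4 h and 42 at 48 h, out of 12422. Fitting the 3 experiments as a block gave 10, 45 and 158, and every probe set called without the block was called with it at these times. These counts share the spread of all 6 groups, and the 6 compared arrays alone gave 3, 0 and 0 by limma. In that fit 794 probe sets at 4 h and 637 at 48 h had an unadjusted p below 0.05. Chance alone would give 621 of the 12422 if the arrays were not paired, and the number at 48 h is close to that. That fit leaves out the pairing by experiment, which can lower such counts. With the block over all 18 arrays, 1283 at 4 h and 1284 at 48 h had an unadjusted p below 0.05. Among the genes past the threshold were Socs3 at 30 min, Socs2, Cish and Pik3r1 at 4 h, and Socs2, Klf5, Igfbp3 and 1 of the Igf1 probe sets at 48 h. Where a control signal lies near background, as for Igf1, Igfbp3, Klf5 and Socs2, the size of the change depends on the 25 added to each signal. Changes are given as log2 change ± standard error and signals as mean ± SD over 3 arrays.

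After 30 min, GH raised the RNA of Socs3 and Socs1, which encode feedback inhibitors of cytokine receptor signalling, and of Rgs16, which encodes a regulator of G-protein signalling. No gene fell past the threshold without the replicate block, and with it 1 of 10 probe sets called was lower. The immediate early transcription factors Fos, Egr2 and Egr1 had higher mean signals with GH, but none of these passed on its own. Socs3 changed by 3.10 ± 0.21 (adjusted p = 1.35e-06), from a signal of 475 ± 25.1 to 4300 ± 775, on an _f_at probe set that can read related transcripts. Its other probe set gave 3.98 ± 0.48 (adjusted p = 0.00234). Rgs16 changed by 1.78 ± 0.24 (adjusted p = 0.00623, signal 770 ± 185 to 2670 ± 364) and by 1.82 ± 0.22 on its other probe set (adjusted p = 0.00234), and Socs1 by 1.39 ± 0.22 (adjusted p = 0.0246, signal 241 ± 7.45 to 681 ± 137). Each of these rises was seen in 3 of 3 experiments.

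The genes next in line at 30 min are mostly immediate early genes, and all had the same sign in 3 of 3 experiments. Fos had a signal of 6280 ± 1400 with GH and 1770 ± 1280 without (2.02 ± 0.39, adjusted p = 0.173), Ier3 9350 ± 3240 and 2820 ± 381 (1.67 ± 0.37, adjusted p = 0.386), and Egr2 1.69 ± 0.31 (adjusted p = 0.104). With the replicate block, Fos (adjusted p = 0.0421) and Ier3 (0.00247) passed, as did Phlda1 (2.26 ± 0.51; 0.386 without the block, 0.0108 with it) and Zfp36 on an _s_at probe set (1.41 ± 0.43; 1 without, 0.041 with), the last of these picked after the values were seen. Egr1, at 1.11 ± 0.37, and Pim3, at 0.85 ± 0.23, passed in neither model. The 6 lowest unadjusted p-values for a lower signal belonged to Epop (-1.08; an _r_at probe set), Acadvl (-0.95), Slc27a5 (-1.09), Spn (-1.07), Nr6a1 (-0.65) and Ugt2b5 (-1.19; an _f_at probe set), with adjusted p of 0.175 to 0.825. All 6 had both group means near background.

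As a group, 30 of 33 immediate early genes were higher with GH at 30 min, with a mean change of 0.64 (camera, adjusted p = 1.38e-27, adjusted p = 0.00183 with an estimated correlation). None of the 33 passed over all probe sets by limma, where 15 had an unadjusted p below 0.05, and 15 rose adjusted over the list alone. These were Fos, Egr1, Egr2, Ier3, Phlda1, Zfp36, Junb, Btg2, Ccn1, Dusp6, Gadd45g, Ier2, Klf2, Klf4 and Myc, all but the 4 with the lowest p named after the values were seen. SOCS family and STAT5 targets also passed upward (17 measured, adjusted p = 0.000125; 0.00667 with an estimated correlation). In that list 2 genes rose over all probe sets, Socs3 and Socs1, and 3 adjusted over the list alone, with Pim3 added. Its mean was 0.29 and its median -0.07, so the call rests on a few members. GH response genes followed at every time passed upward with Fos and Socs3 foremost (22 measured; 1 rose over all probe sets, 2 over the list alone; mean 0.44, adjusted p = 4.15e-07), a call lost at adjusted p = 0.102 with an estimated correlation and kept at 0.0066 with that and the block. Inflammatory and acute-phase genes had 20 of 27 members higher (mean 0.24, adjusted p = 0.00171) but 0 past the threshold by limma over all or within the list, 1 with an unadjusted p below 0.05, and adjusted p = 0.371 with an estimated correlation (0.0289 with that and the block). In simulations without effect, the preset test still called a mean of 3.4 lists here, against 4 found. With the block it called a mean of 2.1 and at most 6, against 5 found. The shuffling behind the 3.4 does not keep the experiments balanced, so that mean can be too high for the real groups.

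After 4 h, GH raised the RNA of Socs2 and Cish, further feedback inhibitors of cytokine signalling, and of Pik3r1, which encodes the regulatory subunit of the lipid kinase activated by insulin. Adipor2, encoding an adiponectin receptor, Gja1, encoding a gap junction connexin, and Gadd45g, a growth-arrest gene, rose as well. Myc fell. The fat cell genes Lpl, Adipoq and Pparg did not pass. All calls had the same sign in 3 of 3 experiments. Socs2 changed by 3.65 ± 0.37 (adjusted p = 0.00052, signal 60.4 ± 28.8 to 1060 ± 472), Cish by 2.50 ± 0.28 (0.000816, signal 139 ± 53.5 to 874 ± 46) and Pik3r1 by 2.41 ± 0.30 (0.0016, signal 159 ± 24.9 to 1040 ± 519). Gadd45g changed by 2.27 ± 0.37 (adjusted p = 0.0244), Gja1, on an _f_at probe set, by 1.95 ± 0.21 (0.000529), Rap1gap by 1.54 ± 0.28 (0.0457) and Rgs16 by 1.46 ± 0.24 (0.0254). Ppa1, encoding an inorganic pyrophosphatase, rose from an already high 5400 ± 1230 to 13700 ± 3030 (1.34 ± 0.23, adjusted p = 0.0254). Nabp1 changed by 1.37 ± 0.19 (adjusted p = 0.00412), Gdf5, a growth factor of the bone morphogenetic protein family, by 1.30 ± 0.19 (0.00889), and Adipor2 by 1.25 ± 0.15 (0.00127, signal 2160 ± 125 to 5190 ± 584). Chic1 (1.04 ± 0.19, adjusted p = 0.0429) is near background in both groups. Atf3, named after its values were seen, rose on an _r_at probe set (1.85 ± 0.32, adjusted p = 0.0334) and had 1.68 ± 0.42 on an _f_at probe set (adjusted p = 0.277; 0.0308 with the block). Other probe sets passed for neither Gja1 (1.07, near background) nor Rgs16 (1.15 ± 0.22, adjusted p = 0.0779, with the block 0.0434). Myc was the only call downward (-1.11 ± 0.17, adjusted p = 0.0103, signal 441 ± 75.9 to 191 ± 37.3).

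Other genes at 4 h reached the threshold only with the replicate block, which raised the count from 15 to 45 probe sets, 31 higher and 14 lower. Bcl6, a transcriptional repressor, had -1.87 ± 0.44 (adjusted p = 0.232, with the block 0.00278, signal 1870 ± 693 to 531 ± 296). Gadd45a (-1.47 ± 0.29, adjusted p = 0.0779, with the block 0.0412), Ezh1 (-0.89, 0.0779 and 0.0379) and Septin10 (-1.12, 0.113 and 0.0464) went the same way. Notch1 (-1.02, 0.113 and 0.0606) and Zmynd8 (-0.85, 0.181 and 0.0697) passed in neither model. Igf1 on its dimmer probe set, of the _g_at kind, had 1.77 ± 0.43 (adjusted p = 0.277, with the block 0.00166, signal 35.3 ± 26.2 to 183 ± 103), while its brighter probe set had 0.25. Abhd5 (0.84, with the block 0.0351), Ifi35 (0.72, 0.0401) and Igtp (1.29, 0.0426) passed upward with the block only, as did Tbc1d14 (0.94, 0.00252) and Fkbp11 (1.17, 0.00635), both picked after the values were seen. Among genes of stored fat and its hormones, Lpl had -0.08, Fasn -0.05, Adipoq -0.01 and Pparg -0.16, the last from an _s_at probe set.

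At 4 h, 6 of the 24 lists passed with the preset correlation and 0 with the estimated one, so each of these calls is open. A mean of 3.5 were called in simulations without effect, whose shuffling does not keep the experiments balanced. With the block 5 passed, against a mean of 1.95 and at most 7. SOCS family and STAT5 targets were higher (mean 0.40, adjusted p = 0.0103, adjusted p = 0.104 with an estimated correlation). Of its 17 members 2 rose over all probe sets, Cish and Socs2, and adjusted over the list alone these 2 rose and 1, Bcl6, fell. Heat shock genes were higher (10 of 14; mean 0.34, adjusted p = 0.00228, adjusted p = 0.104 with an estimated correlation), with 0 past over all probe sets by limma, 5 with an unadjusted p below 0.05, and 2 rising over the list alone, Hsph1 (1.10 ± 0.30) and Dnaja1 (0.75). For sterol synthesis and uptake, 16 of 18 were higher, led by Sqle (1.19 ± 0.56) and Dhcr7 (0.81) (mean 0.42, by experiment 0.63, 0.70 and -0.07, adjusted p = 0.00645, adjusted p = 0.768 with an estimated correlation). None of the 18 passed over all or within the list by limma, where 2 had an unadjusted p below 0.05, and 4 rose over the list alone with the block, Dhcr7, Idi1, Msmo1 and Sqle. Ribosome biogenesis and polyamine synthesis had 17 of 20 higher (mean 0.21, by experiment 0.47, 0.40 and -0.23, adjusted p = 0.0103, adjusted p = 0.68 with an estimated correlation), 0 past over all by limma with 4 unadjusted, and 2 over the list alone, Noc4l (0.75) and Bop1 (0.57).

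The other 2 lists that passed at 4 h were lower. Inflammatory and acute-phase genes such as Cxcl1 (-1.18), Cxcl5 (-0.92), Ptx3 (-0.84) and Vcam1 (-0.60) had 22 of 27 members lower (mean -0.26, adjusted p = 0.0267, adjusted p = 0.68 with an estimated correlation), 0 past over all or within the list by limma and 1 unadjusted. GH receptor and JAK-STAT components, with Stat5a at -0.47 and Stat3 at -0.61, had 13 of 20 lower (mean -0.15, adjusted p = 0.0418, adjusted p = 0.68 with an estimated correlation, and 0.0724 with the block). None of these passed over all or within the list by limma and 3 did unadjusted. GH response genes followed at every time did not pass (adjusted p = 0.619; mean 0.25, median -0.06). In that list 3 rose over all probe sets, Socs2, Cish and Pik3r1, and adjusted over the list alone 4 rose, with Atf3 added, and 3 fell, Bcl6, Junb and Stat5a. Of the immediate early genes Gadd45g rose and Myc fell over all probe sets.

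**Figure D1:**
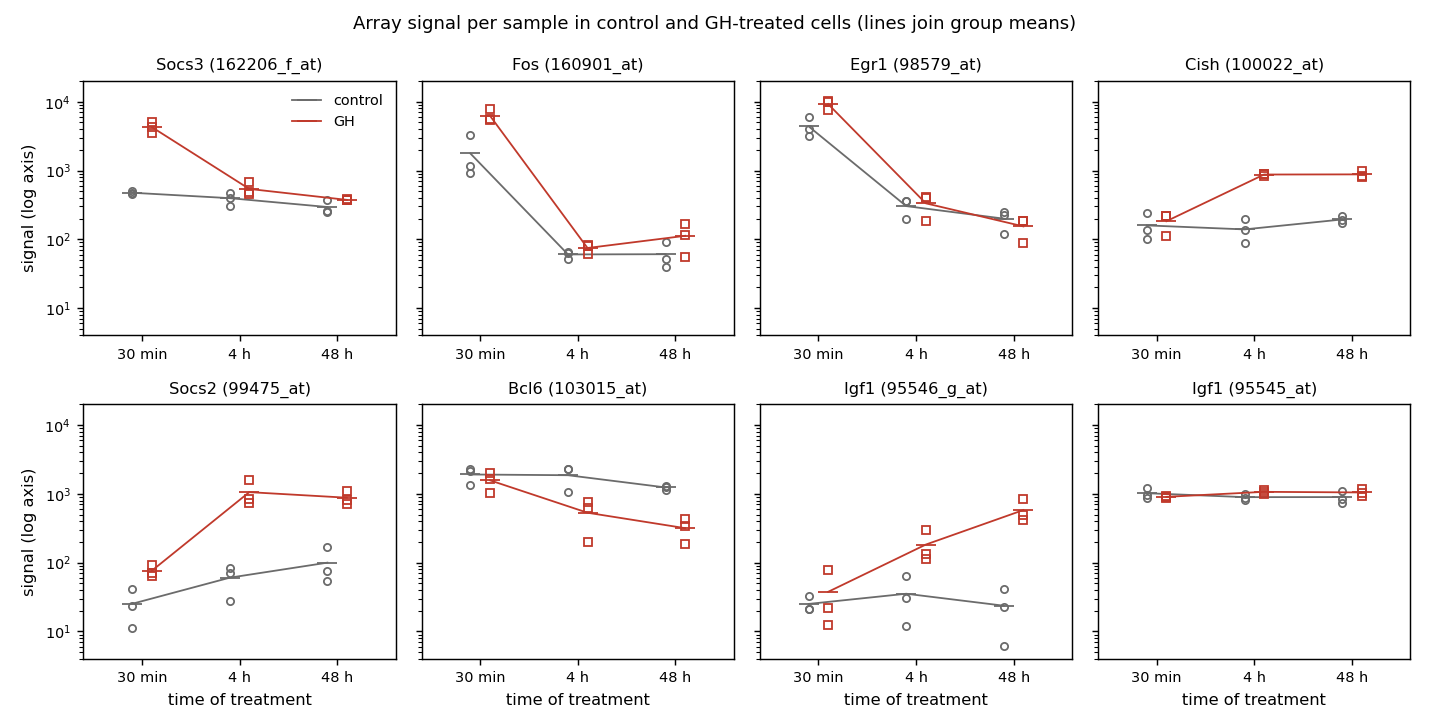
Signal of Socs3, Fos, Egr1, Cish, Socs2, Bcl6 and both Igf1 probe sets on each array, in control (circles) and GH (squares). Lines join the group means.

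After 48 h, GH raised RNA for Igfbp3, a carrier of insulin-like growth factors. Of the Igf1 probe sets the dimmer one rose and the brighter one, which stands for the gene in the lists, did not pass. It also raised RNA for the GH receptor itself and for Klf5, a transcription factor of fat cell differentiation. Socs2, Cish, Rgs16, Gadd45g, Adipor2 and Nabp1 stayed raised. RNA for the antigen-presenting molecule Cd1d1, the matrix protein Postn and the desaturase Scd2 fell. Socs2 changed by 2.95 ± 0.37 (adjusted p = 0.00145, signal 99.8 ± 62.4 to 878 ± 199), Klf5 by 2.67 ± 0.47 (0.0218, signal 80.8 ± 64.9 to 556 ± 31.1), Igfbp3 by 2.49 ± 0.33 (0.00274, signal 28.4 ± 7.55 to 287 ± 106) and the chemokine Ccl6 by 2.23 ± 0.36 (0.0133). Gadd45g changed by 2.13 ± 0.37 (adjusted p = 0.0218), Cish by 2.04 ± 0.28 (0.00319), Rgs16 by 1.99 ± 0.24 (0.00145) and Agt, encoding angiotensinogen, by 1.97 ± 0.38 (0.0342, signal 4150 ± 2060 to 15100 ± 4160). Pdlim1 (1.53 ± 0.27, adjusted p = 0.0218), Mpp1 (1.42 ± 0.27, 0.0303), Adipor2 (1.39 ± 0.15, 0.000638, signal 2310 ± 125 to 6090 ± 163) and Nabp1 (1.38 ± 0.19, 0.0028) complete the 12 genes that the rule names upward, each on its brightest probe set. All calls by limma at 48 h in this and the next paragraph had the same sign in 3 of 3 experiments.

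Cd1d1 fell most among genes past the threshold (-1.85 ± 0.18, adjusted p = 0.000383, signal 751 ± 140 to 189 ± 26.4), followed by Postn, which encodes periostin (-1.65 ± 0.25, adjusted p = 0.00776, signal 4910 ± 1020 to 1620 ± 690), and the interferon-induced Ifi27l2a (-1.37 ± 0.24, adjusted p = 0.0229). Dusp6, encoding an ERK phosphatase, fell by 1.33 ± 0.21 (adjusted p = 0.0111), Gstz1 by 1.28 ± 0.19 (0.00776), Klf4 by 1.05 ± 0.18 (0.0185), Anxa1 on an _f_at probe set by 1.00 ± 0.19 (0.0298) and Myc by 0.98 ± 0.17 (0.0185). Scd2 had the highest signal among them (-0.88 ± 0.17, adjusted p = 0.0303, signal 19000 ± 1830 to 10400 ± 1680). Named after the values were seen, Igf1 rose 3.65 ± 0.43 on its dimmer _g_at probe set (adjusted p = 0.00144, signal 23.6 ± 18 to 582 ± 224) and had 0.23 ± 0.17 on its brighter one (adjusted p = 0.921). Ghr rose 1.16 ± 0.21 on 1 probe set (adjusted p = 0.0238, signal 2520 ± 530 to 5570 ± 407) and had 1.40 ± 0.35 on its brighter _s_at probe set (adjusted p = 0.135, with the block 0.00112). The cell-cycle inhibitor Cdkn1a (1.20 ± 0.22, adjusted p = 0.0298), the stress-response factor Xbp1 (1.10 ± 0.21, adjusted p = 0.0312) and the desaturase Fads1 (1.08 ± 0.21, adjusted p = 0.0303) also rose. Other probe sets of some genes called at 48 h did not pass by limma. Igfbp3 had 1.49 ± 0.72 (adjusted p = 0.772). Pdlim1 had 0.54 (adjusted p = 0.649) and Cdkn1a 0.43 ± 0.28 (0.886), both with the same sign in 2 of 3 experiments. Scd2 had -0.31 ± 0.21 (adjusted p = 0.896), and Anxa1 -1.06 (0.26) and -1.11 (0.187, with the block 0.0457). Dusp6 had -0.63 and Klf4 0.14, both near background. Atf3 rose on its _r_at probe set (1.80, adjusted p = 0.0237) and had 1.28 on its _f_at one (0.393, with the block 0.0455).

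The replicate block raised the count at 48 h from 42 to 158 probe sets, 86 higher and 72 lower, and each gene named here that it adds had the same sign in 3 of 3 experiments. Among interferon-response genes these were Psmb9 (2.20 ± 0.47, adjusted p = 0.0658, with the block 0.00396), Tap1 (1.13, 0.373 and 0.00669), Ifi35 (0.87, 0.153 and 0.00669) and Psmb8 (0.85, 0.69 and 0.0197). Among matrix genes they were Mmp3 (-2.29 ± 0.71, 0.331 and 0.0118), Thbs2 (-1.88 ± 0.40, 0.0591 and 0.0155), Lox (-1.50 ± 0.33, 0.0769 and 0.00734), Dcn (-1.11 ± 0.28, 0.141 and 0.00838), Col3a1 (-1.15, 0.619 and 0.038), Lum (-1.56, 0.67 and 0.0494) and, upward, Col6a3 (0.61 ± 0.18, 0.307 and 0.0494). Bcl6 had -1.95 ± 0.44 (adjusted p = 0.0815, with the block 0.00145, signal 1240 ± 86.3 to 317 ± 121) and the IGF carrier Igfals 2.09 ± 0.61 (0.262 and 0.00186). The chemokines Cxcl1 (-1.45, 0.0815 and 0.0176), Cxcl5 (-1.62, 0.196 and 0.0457) and Ccl7 (-1.42, 0.642 and 0.0458), the acute-phase gene Ptx3 (-1.31, 0.41 and 0.0294) and the sterol genes Hmgcs1 (-1.13, 0.781 and 0.0223), Idi1 (-1.29, 0.761 and 0.025) and Fdps (-0.86, 0.845 and 0.0487) were lower. Pik3r1 had 1.14 (0.172 and 0.0211), Igf2 0.89 (0.285 and 0.0345), the phosphatase gene Ptpn1 0.79 (0.649 and 0.016), Elovl5 0.59 (0.206 and 0.0421), Pck1 -1.77 (0.234 and 0.0379) and Retn -0.58 (0.845 and 0.0434). Mmp3, Col3a1, Lum, Col6a3, Pck1 and Retn were picked after the values were seen. Fasn, at -1.24 ± 0.29, passed in neither model (adjusted p = 0.101, with the block 0.0698), nor did Lipe (-0.63, 0.427 and 0.0919), and Lpl (-0.36), Adipoq (0.03) and Pparg (0.03) were little moved.

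At 48 h, 8 of the 24 lists passed with the preset correlation, where a mean of 4.15 were called without effect, and 2 passed with the estimated correlation. With the block 9 passed, against a mean of 2.75 and at most 6 in simulations without effect, and 2 of them with the estimated correlation. These 2 were the IGF axis (9 of 12 higher, mean 0.60, adjusted p = 0.000613; 0.0225 with an estimated correlation) and SOCS family and STAT5 targets (12 of 17 higher, mean 0.49, adjusted p = 0.000862; 0.0225 with an estimated correlation). Of the IGF axis 1 gene rose over all probe sets, Igfbp3, and 4 adjusted over the list alone, with Igf2, Igfals and Igfbp7 added. Igf1 enters this list by its brighter, unmoved probe set. Of the SOCS family and STAT5 targets 3 rose over all probe sets, Cdkn1a, Cish and Socs2, and adjusted over the list alone 4 rose, with Igfals added, and 1 fell, Bcl6. Interferon-response genes were higher (21 of 26, mean 0.44, adjusted p = 0.00114), with 0 past over all probe sets by limma, 6 unadjusted and 2 over the list alone, Ifi35 and Psmb9. That call gave adjusted p = 0.666 with an estimated correlation, which was 0.74 between members. The correlation was estimated without the block, so it includes shifts between experiments. The mean change by experiment was 0.41, 0.41 and 0.51. In the controls, the list's mean centred log2 level fell from 4 h to 48 h in each experiment (-0.012 to -0.348, 0.593 to -0.264 and -0.624 to -1.167). With GH it went from -0.051 to 0.064, 0.608 to 0.141 and -0.45 to -0.659.

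The remaining 5 lists were lower at 48 h, and each lost its call with an estimated correlation. Extracellular matrix genes were lower in 25 of 32 (mean -0.46, adjusted p = 6.9e-05, adjusted p = 0.299 with an estimated correlation). Postn alone fell over all probe sets, and adjusted over the list alone 6 fell, Postn, Thbs2, Lox, Dcn, Mmp3 and Col18a1, and 1, Col6a3, rose. Lipolysis and lipid droplet genes were lower in 14 of 17 (mean -0.31, adjusted p = 0.000883, adjusted p = 0.299 with an estimated correlation), with 0 past over all by limma, 4 unadjusted downward and 1 over the list alone, Cd36 (-0.79). Preadipocyte and fibroblast markers such as Pdgfrb (-0.81) and Pdgfra (-0.90) were lower in 15 of 18 (mean -0.39, by experiment -0.64, -0.77 and 0.25, adjusted p = 0.00359, adjusted p = 0.299 with an estimated correlation), with 0 past over all or within the list by limma and 3 unadjusted. Inflammatory and acute-phase genes were lower in 19 of 27 (mean -0.34, adjusted p = 0.00359, adjusted p = 0.299 with an estimated correlation), with 0 past over all by limma, 6 unadjusted and 2 over the list alone, Cxcl1 and Cxcl5. Sterol synthesis and uptake, higher at 4 h, was lower in 14 of 18 (mean -0.37, adjusted p = 0.0163, adjusted p = 0.666 with an estimated correlation), with 0 past over all or within the list by limma and 1 unadjusted. GH response genes followed at every time did not pass (adjusted p = 0.645), with 2 rising over all probe sets, Cish and Socs2, and over the list alone 5 rising, with Atf3, Ghr and Pik3r1, and 3 falling, Bcl6, Fasn and Lipe.

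The means of sterol synthesis and of ribosome biogenesis at 4 h and of preadipocyte markers at 48 h had the other sign in experiment 3, while the other lists past the threshold had the same sign in 3 of 3 experiments.

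**Figure D2:**
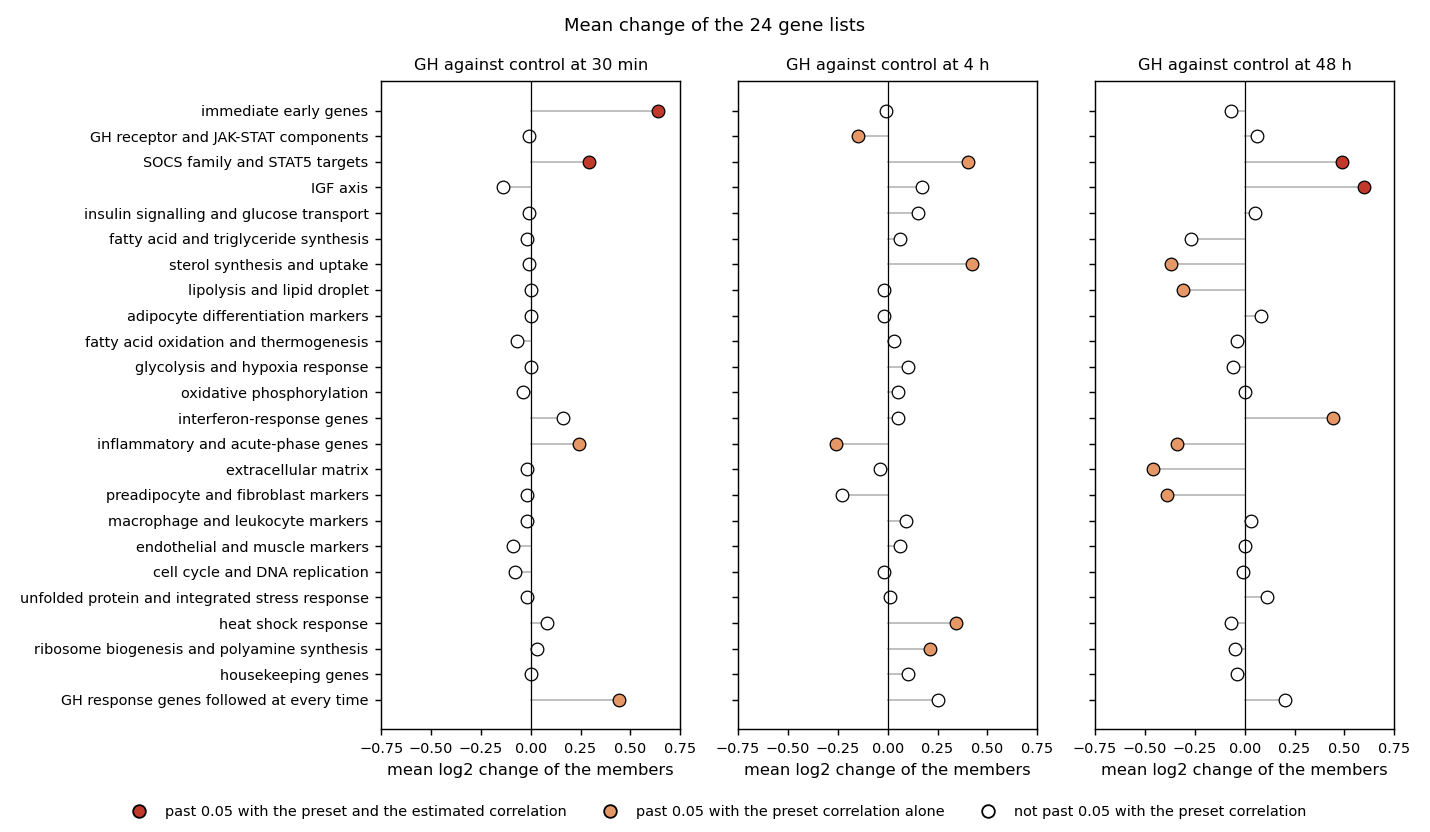
Mean log2 change of the members of each of the 24 lists at each time. Red marks lists past the threshold with the preset and the estimated correlation, orange with the preset one alone, and open circles lists not past.

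**Figure D3:**
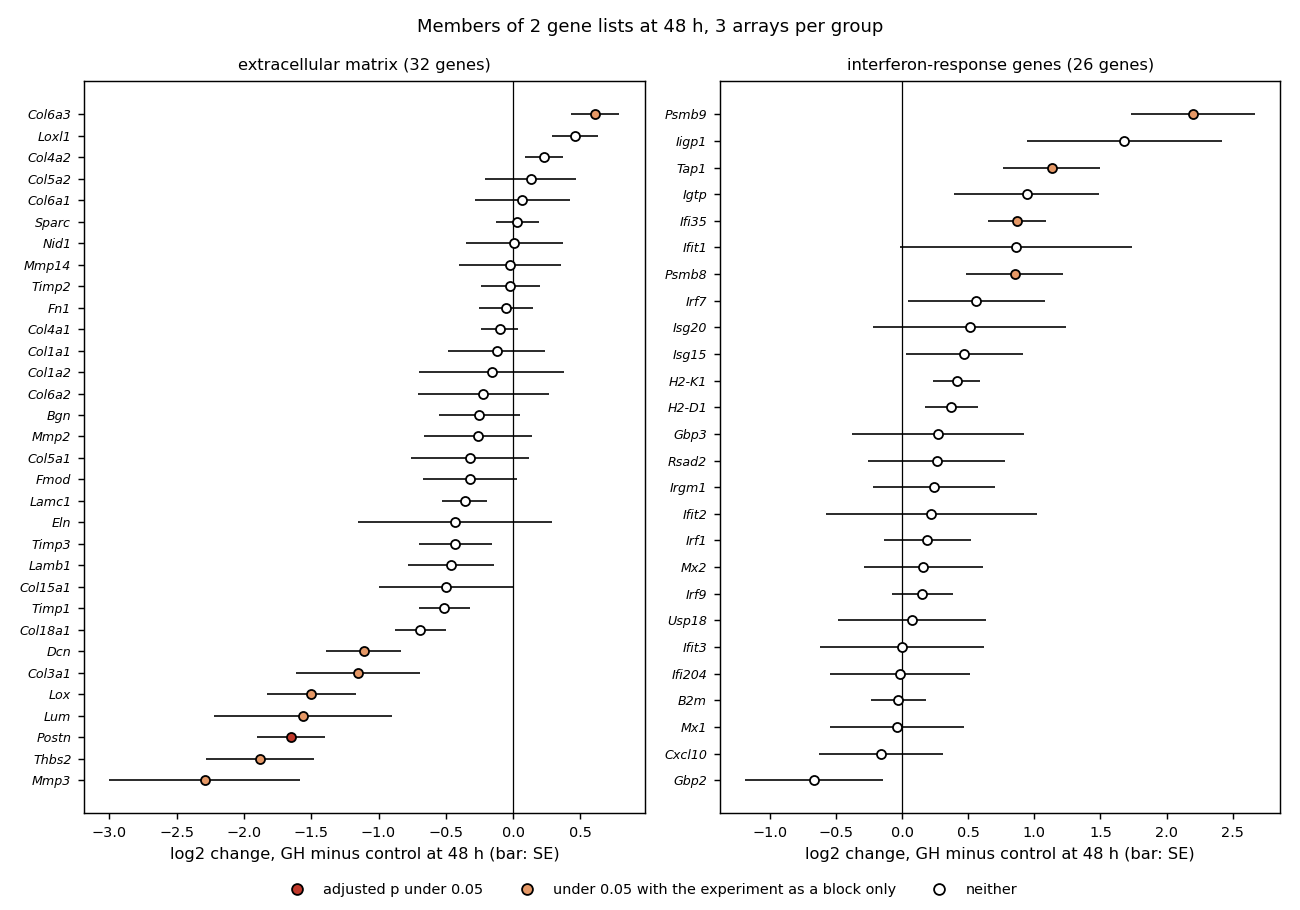
Log2 change ± standard error at 48 h for extracellular matrix and interferon-response genes. Red marks adjusted p under 0.05, orange this with the replicate block only.

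The remaining lists passed camera's test at no time, although single members changed. Fatty acid and triglyceride synthesis came nearest, at 48 h (18 measured; mean -0.27, adjusted p = 0.0507, with the block 0.0235, and adjusted p = 0.523 with an estimated correlation and the block), where Fads1 rose and Scd2 fell over all probe sets and, over the list alone, 2 rose, Fads1 and Elovl5, and 4 fell, Fasn, Pck1, Pgd and Scd2. For the unfolded protein and integrated stress response (24 measured; lowest adjusted p = 0.17), Xbp1 rose at 48 h over all probe sets and over the list alone. In adipocyte differentiation markers (17 measured; 0.939 at the lowest), Adipor2 rose at 4 h and 48 h and Agt at 48 h, and in insulin signalling and glucose transport (17; 0.558), Pik3r1 rose at 4 h. Cdkn1a alone rose at 48 h within cell cycle and DNA replication (35; 0.939). The other lists had no member past over all probe sets at any time: fatty acid oxidation and thermogenesis (21; 0.274), where Acadvl was lower at 30 min and higher at 4 h over the list alone, glycolysis and hypoxia response (20; 0.172), oxidative phosphorylation (25; 0.939), macrophage and leukocyte markers (18; 0.619), endothelial and muscle markers (17; 0.663) and housekeeping genes (13; 0.625). In these lists with small changes, the mean, the median and the test differed in sign in places, as for cell cycle and DNA replication at 48 h (mean -0.01, median 0.04, test upward).

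The GH effect itself differed between times for Socs3 and Myc. From 30 min to 4 h the effect on Socs3 went from 3.10 to 0.42 (difference -2.67 ± 0.29, adjusted p = 0.00137), and that on Myc from 0.60 to -1.11 (difference -1.71 ± 0.24, adjusted p = 0.0148). All differences between times given here had the same sign in 3 of 3 experiments. Those for Socs3 and Myc were the only 2 by limma between 30 min and 4 h, and the block gave 9. Between 48 h and 4 h only the effect on Gja1, read by an _f_at probe set, differed (-2.20 ± 0.29, adjusted p = 0.0194), and not with the block (0.0597). In simulated data, tests of a difference between times found 8.2% to 10.6% of 2-fold and 43.7% to 46.9% of 4-fold changes. A missing call therefore does not show that the effects were alike. Between 48 h and 30 min 8 probe sets differed, 2 upward and 6 downward, and 22 with the block. Downward these were Socs3 (-2.75, adjusted p = 0.00092), Dusp6 (-2.18, 0.00814), Cd1d1 (-1.95, 0.00814), Myc (-1.59, 0.015), Klf4 (-1.56, 0.0277) and the other Socs3 probe set (-3.92 ± 0.68, 0.0493). Upward were Adipor2 (1.31, adjusted p = 0.0277) and an unnamed _f_at probe set (3.41 ± 0.48, 0.00814). Igf1 on its _g_at probe set, named after its value was seen, had 3.46 ± 0.61 (adjusted p = 0.0552, with the block 0.000255).

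The calls at 4 h and 48 h shared 8 genes, all moving the same way at both times. Socs2, Cish, Rgs16, Gadd45g, Nabp1, Adipor2 and Atf3 rose at both and Myc fell at both. With the block 22 probe sets were shared, 19 upward and 3 downward. Independent calls would give 0.035 shared upward and 0.00089 downward without the block. The calls are not fully independent, since both tests use 1 spread per probe set estimated from all 18 arrays. These values are therefore no test of the overlap. Rgs16 rose at all 3 times and was the only gene called at 30 min that was also called later. The correlation of the 4 h and 48 h changes over all probe sets was 0.18.

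In the control cells, immediate early genes were much higher at 30 min than at 4 h. At 4 h against 30 min, Fos had -4.17 ± 0.39 (adjusted p = 0.000108, signal 1770 ± 1280 to 60.2 ± 6.81), Egr1 -3.74 ± 0.37 (0.000108) and Ier2 -3.06 ± 0.30 (0.000108), in 3 of 3 experiments. Ccn1 (-2.91 ± 0.37, adjusted p = 0.00191), Egr2 (-2.56 ± 0.31, 0.00141) and Junb on an _r_at probe set (-2.36 ± 0.41, 0.0392) followed. Dusp1, Ier3, Klf6 and Nr4a1 were lower too, so that 10 of the 11 probe sets called were listed immediate early genes. The other one, Prp2, had adjusted p = 0.0463 and lost its call with the block (0.057). Controls at 48 h and 4 h differed in 0 probe sets by limma. An unadjusted p below 0.05 was seen in 512 without the block and in 948 with it, against 621 expected by chance. The missing calls therefore do not show that these controls were alike. With the block 1 differed, the metallothionein gene Mt2 (-1.71, adjusted p = 1 without the block, 0.000656 with it).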

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

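The comparison of splits without the block and the tests for a difference between times were chosen before the data were examined, while the splits with the block, the sorting of the drawn splits and the tests of the 3 patterns below were chosen after the result was seen. The effect of GH differed between times for Socs3, Myc, Gja1, Cd1d1, Dusp6, Klf4, Adipor2 and 1 unnamed probe set, by limma's test of the difference itself. Between 4 h and 30 min, the difference was -2.67 for Socs3 (adjusted p = 0.00137, with the block 0.00543), whose effect went from 3.10 to 0.42, and -1.71 for Myc (0.0148 and 0.00753), from 0.60 to -1.11. Between 48 h and 4 h it was -2.20 for Gja1 (0.0194 and 0.0597), from 1.95 to -0.25. Between 48 h and 30 min it was -2.75 for Socs3 and -3.92 for its other probe set, -2.18 for Dusp6 (from 0.85 to -1.33), -1.95 for Cd1d1 (from 0.10 to -1.85), -1.59 for Myc, -1.56 for Klf4 (from 0.51 to -1.05), 1.31 for Adipor2 (from 0.08 to 1.39) and 3.41 for the unnamed probe set (from -0.96 to 2.45), each called with the block as well.

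For GH against control and for the controls over time, the 6 arrays make 10 splits, too few for a share under 0.05. The real split called 5 probe sets at 30 min and the highest other 0, at 4 h 15 and 1, at 48 h 42 and 5, for controls at 4 h against 30 min 11 and 1, and for controls at 48 h against 4 h 0 and 0. The number of splits with a result as large was 1 for each but the last, where it was 10. For lists it was 6 at 30 min (real 4, highest other 9), 5 at 4 h (6 and 12) and 1 at 48 h (8 and 7). The splits of 30 min and 4 h arrays that called the most lists do not part all 3 pairs of 1 experiment, so list counts carry a structure of the samples that goes with the experiment. Among the 4 splits that part all 3 pairs, with the replicate block, the real one gave 10 probe sets and the highest other 0 at 30 min, 45 and 0 at 4 h and 158 and 0 at 48 h, and for lists 5 and 1, 5 and 3, and 9 and 5. Without the block, these splits gave for lists 4 and 1, 6 and 3, and 8 and 5. For the differences between times, 100 splits were drawn. Chance was not excluded between 4 h and 30 min, where 10 splits gave as many (real 2, highest other 11), or between 48 h and 4 h, where 18 did (real 1, highest other 7). Between 48 h and 30 min 2 splits gave as many (real 8, highest other 13), a share under 0.05 in these draws alone. Each highest other keeps GH and control apart at 1 of the times and so still holds a GH effect, and the draws that mix them at both times gave at most 1, 3 and 2. These draws ignore the pairing. Among the 32 splits that part all 6 pairs, with the block, 2 were as large between 4 h and 30 min (real 9, highest other 19) and 2 between 48 h and 30 min (real 22, highest other 24). The other one as large was both times the split that swaps all pairs of 1 time, which holds the sum of the GH effects, and the rest gave at most 6 and 13. That split tests another GH effect and is likely to be large wherever GH acts. The share of 2 in 32 therefore cannot decide on chance for either difference with the pairs kept. Between 48 h and 4 h the block called 0 by limma, so its splits decide nothing. There 1024 probe sets had an unadjusted p below 0.05, against 621 expected by chance.

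Fos, Egr1, Ier2 and 8 further probe sets were higher in the 30 min controls than in the 4 h controls. A 30 min control that was a GH array under a wrong label is argued against, since each probe set called from 2 experiments was lower in the control of the experiment left out, Socs3 by at least 2.90 log2 in each and Ier2, the lowest, by 0.71 in experiment 3. A transient response shared by all wells soon after the start may explain the pattern and stays open. It needs the same probe sets to stay down afterwards with GH too, but their median change from 4 h to 48 h with GH, -0.18, runs over members that go both ways (from -0.98 to 0.71) and does not decide. The labels give no untreated sample at time 0 and nothing on handling, so it cannot be told apart from a difference in handling.

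Igf1 rose 3.65 log2 at 48 h on its _g_at probe set and had 0.23 ± 0.17 on its other one. Saturation of the flat probe set is argued against, since its mean signal lies at percentile 83.5 of all probe sets. Background noise in the probe set that rose is argued against too, since its lowest GH signal at 48 h was 3.88 times the highest value of the yeast and Bacillus probe sets. A transcript read by only 1 of the probe sets cannot be told apart from a probe set that responds to another RNA, because probe sequences were not analysed here.

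Extracellular matrix genes such as Postn, Thbs2 and Lox were lower with GH at 48 h. The list lost its call by camera with an estimated correlation, and of these genes Postn alone passed without the block. The description of the control array of experiment 3 names another time. A wrong label there is argued against as the only source of the pattern. The list's mean was lower with GH in experiments 1 and 2 as well (-0.57 and -0.73, against -0.10 in experiment 3). These values were among those that picked the list, and they cannot show whether that label is right. A lower share of undifferentiated cells in the GH wells cannot be told apart from lower matrix RNA per cell. Of 18 preadipocyte and fibroblast markers 15 were lower and 0 were called higher by limma, but their mean was higher with GH in experiment 3 (-0.64, -0.77 and 0.25 by experiment), these cells stem from that cell type and no single marker passed, with 3 lower at an unadjusted p below 0.05. An effect of GH on matrix genes remains open as well.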

How the results depend on the processing

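The alternatives that combine the replicate block with another choice were chosen after the data were seen, the others before. Of 353 values for named genes, 55 were past the threshold, and among their 2967 alternative values 4 had the other sign where either value was called, and 81 where neither was. All 4 were other probe sets: Klf4 had 0.14 at 48 h and 0.01 for 48 h against 30 min, and in the controls at 4 h against 30 min Fos had 0.13 and Egr1 0.38. All are near background, with both group means below 106, and the cause was not tested. Of the values of other probe sets, 78 kept direction and side, 44 had the other sign with no call, 13 lost the call and 4 gained it. Quantile normalization kept direction and side of the threshold for 347 of the 353, a halved pseudocount for 351, a doubled one for 350, the replicate block for 319 (33 passed newly, 1 no longer) and omission of the 3 arrays with conflicting labels for 317 (16 no longer passed). Values kept in these counts include those never called. Each of the 55 calls was refitted without each of the 3 experiments, and 119 of these refits, the larger part, lost the call. Among the values not called, 26 refits gained one.

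The replicate block gave 10 probe sets at 30 min (5 without it), 45 at 4 h (15), 158 at 48 h (42), 9 for 4 h against 30 min (2), 0 for 48 h against 4 h (1), 22 for 48 h against 30 min (8) and 1 for controls at 48 h against 4 h (0). Among named genes it changed no call other than those the report gives. With only the compared arrays, which leaves 4 residual degrees of freedom, the counts were 3 at 30 min, 0 at 4 h (794 with an unadjusted p below 0.05), 0 at 48 h (637), 0 for 48 h against 4 h and 3 for controls at 4 h against 30 min. Chance would give 621 with an unadjusted p below 0.05 if the arrays were not paired, and this fit leaves the pairing out. The counts at 4 h and 48 h therefore rest on a spread shared over the 6 groups or on the block.

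Without the 3 arrays with conflicting labels, there were 3 at 30 min, 32 at 4 h, 4 for 48 h against 4 h and 2 for controls at 48 h against 4 h. With groups from the descriptions, there were 0 at 30 min, 2 at 48 h, 0 for 4 h against 30 min, 3 for 48 h against 4 h, 0 for 48 h against 30 min, 0 for controls at 4 h against 30 min and 2 for controls at 48 h against 4 h. A variance trend gave 65 at 48 h, 4 for 4 h against 30 min and 1 for controls at 48 h against 4 h. Removal of probe sets below the 50th percentile, which leaves fewer to adjust over, gave 77 at 48 h, 6 for 4 h against 30 min, 2 for 48 h against 4 h and 1 for controls at 48 h against 4 h, and below the 25th percentile 5 for 4 h against 30 min. For 4 h against 30 min, quantile normalization gave 6 and a doubled pseudocount 8. Apart from smaller or larger numbers of arrays and probe sets, the cause was not tested.

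The block without the 3 arrays gave 192 at 4 h, 142 at 48 h, 13 for 4 h against 30 min, 57 for 48 h against 4 h, 29 for 48 h against 30 min and 4 for controls at 48 h against 4 h. The block without experiment 3 gave 2 at 30 min, 165 at 4 h, 145 at 48 h, 9 for 4 h against 30 min, 21 for 48 h against 4 h, 25 for 48 h against 30 min, 5 for controls at 4 h against 30 min and 1 for controls at 48 h against 4 h. The cause was not tested.

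Leaving out single arrays or whole experiments gave 1 to 7 probe sets at 30 min (1 without experiment 1 or 2). At 4 h it gave 0 to 106: 0 without experiment 1 or 2, 106 without experiment 3, 7 without GH replicate 1 or 2 or control replicate 2, and 38 without GH replicate 3. At 48 h it gave 0 to 103: 0 without experiment 1 or 2, 103 without experiment 3, 18 without GH replicate 1 or 2 or control replicate 1, 16 without control replicate 2 and 64 without GH replicate 3. For 4 h against 30 min it gave 0 to 9: 0 without experiment 1 or 2, 9 without GH 4 h replicate 3, 5 without control 30 min replicate 2, and 1 without GH 4 h replicate 2, GH 30 min replicate 2, control 4 h replicate 1 or control 30 min replicate 1 or 3. For 48 h against 4 h it gave 0 to 18: 18 without experiment 3, 4 without GH 4 h replicate 3, 2 without GH or control 48 h replicate 3, and 0 without experiment 1 or 2, GH replicate 1 or 2 of either time or control 4 h replicate 2 or 3. For 48 h against 30 min it gave 0 to 15: 15 without GH or control 48 h replicate 3, 14 without experiment 3, 0 without experiment 1 or 2, 5 without GH 48 h replicate 1, GH 30 min replicate 1 or control 30 min replicate 1 or 2, and 4 without GH 48 h replicate 2, control 48 h replicate 1 or 2 or GH 30 min replicate 2.

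For controls at 4 h against 30 min it gave 1 to 9: 4, 1 and 7 without experiments 1, 2 and 3, 6 without control 4 h replicate 3 or control 30 min replicate 2, and 7 without control 30 min replicate 3. For controls at 48 h against 4 h it gave 0 to 3: 3 without experiment 3, 1 without control 48 h replicate 1 and 2 without replicate 3. Lists numbered 3 to 6 at 30 min, 0 to 5 at 4 h (0 without experiment 1, 2 without experiment 2 or control replicate 2, 3 without control replicate 1) and 5 to 10 at 48 h (5 without experiment 1). The estimated correlation gave 2, 0 and 2 lists at the 3 times, fry 2, 2 and 3, and the block with the estimated correlation 0 at 4 h and 2 at 48 h. Groups from the descriptions gave 1 list at 30 min and 3 at 48 h, and the mean over all probe sets of a gene 3 at 4 h. Signal over background limits what can be found: in simulated data 30.8% of 2-fold changes at 4 h were found, and 91.1% of 4-fold changes among brighter probe sets against 65.6% among all.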
